A study of Mus musculus with 6 samples.

How the data were processed

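RNA was measured in 6 libraries of mouse OT-I CD8 T cells, whose transgenic receptor recognises the ovalbumin peptide SIINFEKL. The labels name 3 libraries CD73 KO and 3 WT. Per the labels' protocols, splenic CD8 T cells received the peptide at 10 ng/mL every day for 5 days with IL-7 at 5 ng/mL and IL-15 at 5 ng/mL and were replated after 48 hours. Live cells were sorted before RNA extraction, and libraries came from a strand-preserving kit. The labels do not say whether the 3 libraries of a genotype came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

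The deposited values are raw counts of reads per gene, 1 column per library, keyed by mouse Ensembl gene identifiers. The submitters' processing notes name fastp, HISAT2 and featureCounts and the mm10 build. Versions, the strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of a gene and its antisense partner cannot be told apart, and reads that fit a gene and a near-identical copy may be split between them. The table held 49671 genes. A symbol was found for 49326 identifiers in a table of gene names. The 345 identifiers without one took at most 0.015% of the counts of a library. All columns matched a sample. The 13 mitochondrially encoded genes were listed at 0 in all 6 libraries and were not tested. Coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 names, and were found for 12222 tested genes.

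Depth was uneven. Totals ran from 6934150 to 19382950 counts, so that 1 count equals 0.0516 to 0.144 CPM, the count scaled to a common library total, and 3 counts, taken as the detection floor, equal 0.155 to 0.433 CPM. Intervals for single libraries are exact 95% Poisson intervals and cover counting error only. CPM values were scaled with TMM factors.

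Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 12242. Genotypes were compared with edgeR's quasi-likelihood F-test (TMM factors, robust dispersion estimates, the legacy fit), run in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all tested genes, with 0.05 as the threshold. The standard error of a log2 fold change is its size divided by the square root of F. Fold changes are CD73 KO against WT. The 25 gene lists and 8 lists of markers of other cell types were tested with camera of limma 3.58.1 with a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry, which tests for a shared direction and, separately, for change in either direction. Changed genes within 10 Mb of Nt5e were counted against changed genes elsewhere with Fisher's exact test, two-sided, leaving out Nt5e itself. Alternatives were RLE size factors, library size alone, no filter, a filter of 1 CPM in 3 libraries, the edgeR 4 fit, no robust estimation, the replicate number as a block, each replicate left out, DESeq2 1.42.0, limma-voom, and windows of 5 and 20 Mb. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined.

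Named genes were Nt5e, then genes past the threshold without overlap between groups and with a mean of at least 5 CPM, leaving out gene models, pseudogenes and receptor segments. Where fewer than 5 in a direction qualified, the 5 of smallest p in that direction were taken. List members past the threshold and 16 T cell genes named in advance were added. The 4 pseudogenes past the threshold, and the list members given as examples, were named after their values were seen.

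Transcripts of tested processed pseudogenes were matched with blastn to protein-coding transcripts of GENCODE M21, with an E-value limit of 1e-20. The best match covering at least 70% of the pseudogene was taken as its parent. The count of changed genes near Nt5e under other settings than the window, the estimated correlation with a library left out or with the hypoxia covariate, the matching of pseudogenes, the thinning of all libraries to 6934150 counts and a fit with the mean of the hypoxia list as covariate were chosen after seeing the data. The fit was tested on simulated data with 200 genes changed among 12242, at the real library sizes. At the adjusted threshold it recovered 25.4% of genes changed 1.5-fold, 82.1% of genes changed 2-fold and 93.9% of genes changed 4-fold, and 8.22% of its calls were false. Each gene was simulated on its own, without differences shared among genes, so these rates need not hold for the real libraries.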

Results

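Gene expression was compared between OT-I CD8 T cells labelled CD73 KO and cells labelled WT after 5 days of repeated peptide stimulation, a culture meant to drive T cells into exhaustion. CD73, encoded by Nt5e, is the surface enzyme that turns AMP into adenosine. Each genotype had 3 libraries. The CD73 KO libraries held 19382950, 14867558 and 10202128 counts, and the WT libraries held 13039990, 9510879 and 6934150. Trbv12-1, the variable segment of the OT-I receptor beta chain, took 99.0% to 99.7% of the counts of its segment class in each library. No alpha chain segment led in that way. The top one was Trav14-1 in CD73 KO replicate 1 and WT replicate 1 and Trav21-dv12 in the other 4 libraries. It took 12.5% to 16.6% of 216 to 942 counts. Trac, the constant segment of the alpha chain, had 3396 to 10675 counts, far more than all its variable segments together. The variable segment counts therefore do not tell which alpha chain the cells carried. Cd4 had 0 to 5 counts per library and Xist 0 or 1, while the Y-linked gene Ddx3y had 666 to 2073.

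The targeted gene was read first. Nt5e (ENSMUSG00000032420, chromosome 9, 88327197 to 88372092, mm10) had 69, 128 and 88 counts in the CD73 KO libraries and 290, 49 and 263 in those labelled WT. Its level was 6.86 ± 2.77 CPM in CD73 KO (SD, n = 3) and 21.7 ± 16.1 CPM in WT (SD, n = 3). The log2 fold change of -1.67 ± 0.72 (SE) did not pass the test (adjusted p = 0.534). The library labelled WT replicate 2, at 5.21 CPM (95% interval 3.86 to 6.89), lay within the CD73 KO range of 3.67 to 8.46 CPM. Without it the log2 fold change was -2.14 (adjusted p = 0.339). That was the largest drop among the fits that left out a library, whose range is given below. Counts per gene do not show which exons the reads came from, so reads in CD73 KO do not tell whether the allele is intact. Group and replicate names below are those of the labels.

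Between genotypes, 7 of 12242 genes changed, 5 higher and 2 lower in CD73 KO, all at least 2-fold. Mns1, a gene of meiosis and cilia (chromosome 9, 72438011 to 72462025), fell from 53.2 ± 3.64 to 13.5 ± 0.836 CPM (SD, n = 3), a log2 fold change of -1.98 ± 0.13 (adjusted p = 8.39e-05). Cyb5r4, a cytochrome b5 reductase (chromosome 9, 87022014 to 87077774), fell from 116 ± 10.3 to 57.5 ± 8.43 CPM (adjusted p = 0.0284). Bckdhb, a subunit of the enzyme complex that breaks down branched-chain amino acids (chromosome 9, 83925145 to 84124240), rose from 5.77 ± 0.567 to 14.2 ± 1.29 CPM (adjusted p = 0.0495). The adjusted p of Bckdhb was above 0.05 in 11 of 17 alternatives, and those of Cyb5r4 and Gm6548 were above it in 4 of the 6 fits that left out a replicate.

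The other 4 changed genes were processed pseudogenes, retrocopies of the transcript of another gene, and were named after their values were seen. Gm11868 (chromosome 4, 18844202 to 18845679) rose from 0.463 ± 0.177 to 22.1 ± 2.61 CPM, a log2 fold change of 5.51 ± 0.27 (adjusted p = 8.92e-06). Its sequence matched Cyb5r4 at 97.98% identity. Gm13456, Gm5869 and Gm6548 rose with log2 fold changes of 1.32, 1.43 and 1.22 and matched Eef1a1, a translation elongation factor (chromosome 9, 78478449 to 78489151), at 98.56%, 96.48% and 96.66% identity. Eef1a1 itself had a log2 fold change of 0.10 ± 0.10 (adjusted p = 0.770). Reads of a retrocopy and its parent can be exchanged by the counting, so these levels are uncertain. The sum of Cyb5r4 and Gm11868 was 79.6 ± 10.2 CPM in CD73 KO and 116.5 ± 10.5 CPM in WT (SD, n = 3).

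**Figure D1:**
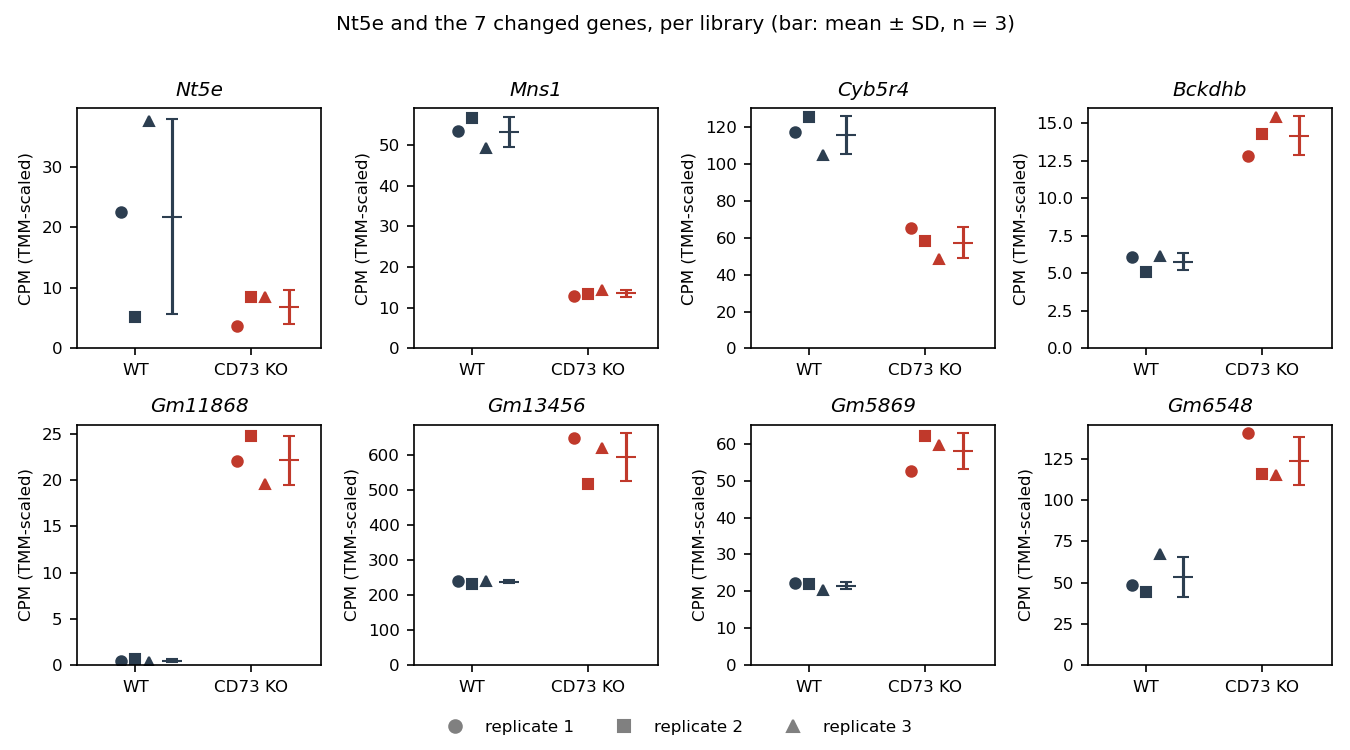
CPM of Nt5e and of the 7 changed genes in each library, by genotype, with the mean and SD (n = 3) beside the points. Nt5e of the library labelled WT replicate 2 lies at the CD73 KO level, while at Mns1 it lies at 56.7 CPM with the other WT libraries.

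With all 6 libraries, changed genes were more frequent near Nt5e than elsewhere. Within 10 Mb of Nt5e, 2 of 71 tested genes changed (Cyb5r4 and Bckdhb), against 5 of 12150 elsewhere (odds ratio 70.1, 95% interval 6.57 to 436, Fisher's exact p = 0.000686, two-sided). This rests on 2 calls that single libraries remove. The fold changes kept their direction, which leaving out a library could hardly reverse, since the groups do not overlap at either gene. Over 17 alternatives the log2 fold change ran from -1.12 to -0.91 for Cyb5r4 and from 1.21 to 1.51 for Bckdhb. Without CD73 KO replicate 2, CD73 KO replicate 3, WT replicate 1 or WT replicate 2, 0 genes within 10 Mb were called by edgeR and the odds ratio was 0 (upper 95% limits 117 to 258); without WT replicate 3 it was 1 gene (odds ratio 24.0), and without CD73 KO replicate 1 it was 2 (57.5). Settings that called more genes gave lower odds ratios, 5.23 without a filter on low counts (9 of 133 genes within 10 Mb) and 6.86 with DESeq2 (4 of 133). Within 20 Mb, 3 of 202 changed, Mns1 included, and 1 without any one of the 4 libraries first named. At an unadjusted p under 0.05 the share was 21.1% of 71 genes within 10 Mb and 9.58% elsewhere (odds ratio 2.53, 95% interval 1.32 to 4.55, Fisher's exact p = 0.00349, two-sided). Leaving out single libraries gave odds ratios from 1.92 to 4.55 by this measure, the highest without WT replicate 2, with Fisher's exact p above 0.05 without CD73 KO replicate 1 (0.0507). It was also above 0.05 without a filter (odds ratio 1.66, Fisher's exact p = 0.0605) and after thinning (odds ratio 1.94, Fisher's exact p = 0.0538). Genes were counted as independent in these tests, which neighbours need not be.

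**Figure D2:**
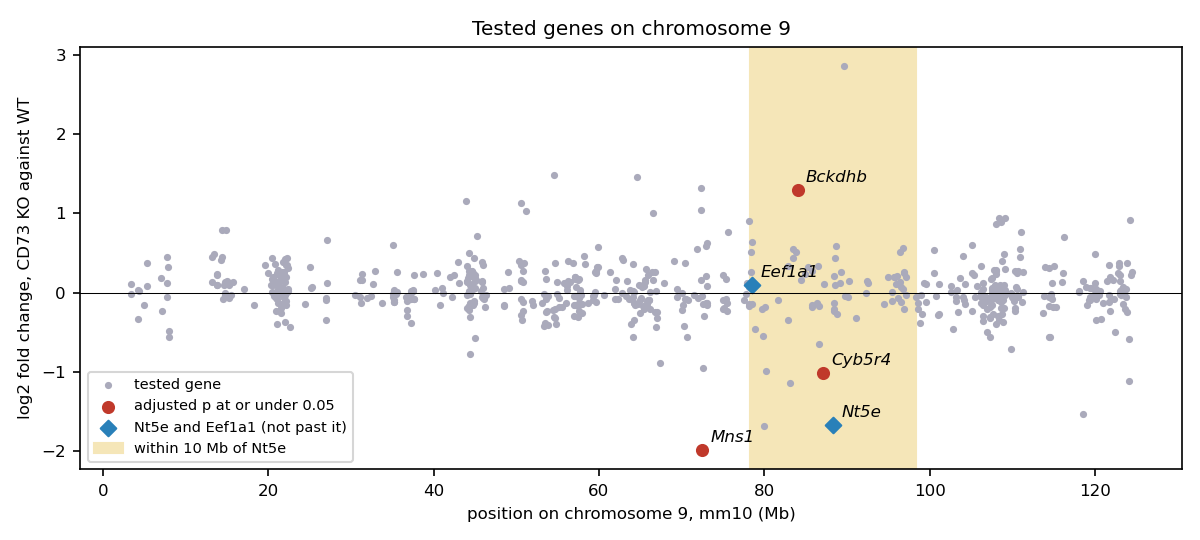
Log2 fold change of each tested gene on chromosome 9 against its position in Mb, with genes at or under an adjusted p of 0.05 in red and the 10 Mb around Nt5e shaded. The 3 changed genes, Mns1, Bckdhb and Cyb5r4, start at 72438011, 83925145 and 87022014.

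Among the T cell genes named in advance, none passed the test. Among receptors that restrain T cells, log2 fold changes were -0.01 ± 0.12 for Tigit, -0.07 ± 0.26 for Ctla4, -0.15 ± 0.40 for Pdcd1 and 0.25 ± 0.11 for Lag3 (adjusted p = 0.518), and the directions of Pdcd1, Ctla4 and Tigit turned when single libraries were left out. Havcr2, which encodes TIM-3, had -1.73 ± 0.62 (adjusted p = 0.492), with 49.5 CPM in the library labelled WT replicate 2 and 22.8 and 7.97 CPM in the other WT libraries. Gzmb, a granule protease, was at 1480 ± 68.9 CPM in CD73 KO and 2857 ± 1019 CPM in WT (adjusted p = 0.287). Tcf7 and Slamf6, genes of stem-like exhausted cells, had 0.77 ± 0.20 and 0.89 ± 0.27 (adjusted p = 0.319 and 0.379). The values were 0.41 ± 0.13 for Tox, -0.37 ± 0.13 for Ifng, 0.48 ± 0.19 for Tnf, -0.77 ± 0.35 for Prf1, -0.66 ± 0.29 for Entpd1, 0.19 ± 0.13 for Adora2a and 0.10 ± 0.13 for Mki67. Il2 was too low to be tested. Mki67 turned to -0.05 without CD73 KO replicate 1.

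The genes of smallest p that missed the threshold were Slfn1 (1.18 ± 0.17, adjusted p = 0.0534), Uba7 (0.87 ± 0.13), Tagap (1.04 ± 0.18) and Scml4 (0.76 ± 0.13) on the higher side. On the lower side they were Emilin2 (-1.71 ± 0.31), Ccng1 (-0.77 ± 0.14) and the amino acid transporter gene Slc7a5 (-0.57 ± 0.12, adjusted p = 0.187). At an unadjusted p under 0.05 there were 1180 genes, 704 higher and 476 lower, where 612 would come by chance. That count was 565 of 12599 genes without the library labelled WT replicate 2, 757 without WT replicate 1 and 1758 without CD73 KO replicate 3, and 1697 when CD73 KO replicate 1 was grouped with WT replicates 1 and 2 against the rest. The groups did not overlap in 15.2% of genes, against 10% by chance. DESeq2 called 99 genes, the 7 included, and edgeR without a filter on low counts called 298.

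Interferon-stimulated genes are those that cells switch on in response to type I interferon. Among the lists they stood out most by the preset camera test and by the median log2 fold change. All 35 members were higher in CD73 KO, with a median log2 fold change of 0.99, and 26 passed when adjusted over the list alone, against 0 over all genes tested. Without CD73 KO replicate 1, 13 passed over the list alone. Examples are Ifi44 (3.93 ± 0.87), Oasl2 (2.58 ± 0.50), Ifit3 (2.12 ± 0.49) and Irf7 (1.30 ± 0.31). The members summed to 3148, 2833 and 2450 CPM in the CD73 KO libraries and 1146, 1711 and 1970 CPM in the WT libraries. The list rose by camera with the preset correlation (adjusted p = 4.37e-37), but not with an estimated correlation (adjusted p = 0.185). Camera with an estimated correlation gave a lower adjusted p of 0.129 to the list of naive, memory and progenitor-exhausted genes. With CD73 KO replicates 1 and 2 and WT replicate 2 grouped against the rest, preset camera also gave the interferon list a low p (unadjusted p = 2.59e-20).

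By the same preset test 13 of 24 lists passed. With an estimated correlation or with fry's directional test 0 did, although 1180 genes had an unadjusted p under 0.05 in edgeR. The preset test also called 5 to 12 lists in every other grouping of the 6 libraries into 3 and 3. Each of those groupings mixes the genotypes, so the preset p-values do not measure a difference of genotype alone. Genes of naive, memory and progenitor-exhausted cells rose, with 24 of 25 members higher and a median of 0.59 (adjusted p = 3.67e-10, and adjusted p = 0.129 with an estimated correlation). Adjusted over the list alone, 6 members passed, Klf2 (1.46 ± 0.37) and Foxo1 (0.41 ± 0.13) among them. Leaving out single libraries gave 0 (WT replicate 1 or 2), 1 (CD73 KO replicate 2, with a median of 0.39), 2 (CD73 KO replicate 1) and 11 (WT replicate 3). Immediate early genes rose, with 29 of 31 higher and a median of 0.35 (adjusted p = 6.88e-07, and adjusted p = 0.230 with an estimated correlation), and Btg2, Egr2 and Spry2 passed when adjusted over the list alone. That count was 0 without CD73 KO replicate 3, WT replicate 1 or WT replicate 2, 2 without CD73 KO replicate 1, and 9 without CD73 KO replicate 2 or WT replicate 3. Linker and core histones rose, with 9 of 9 higher (adjusted p = 0.000133, and adjusted p = 0.185 with an estimated correlation), led by Hist1h1a (1.58 ± 0.31) and Hist1h1b (1.29 ± 0.29). Their median of 0.39 was 0.72 without CD73 KO replicate 2 and 0.68 without WT replicate 3, and 0.79 with the libraries thinned to the smallest total. With all 6 libraries, the filter of 1 CPM in 3 libraries alone moved it to 0.75. These moves therefore need not come from the library left out or from depth. Among the 24 lists, the fry test of change in either direction passed for the histones alone (adjusted p = 0.0383). The cAMP response list rose with 21 of 24 higher (adjusted p = 0.00453) and T cell receptor signalling with 25 of 32 higher (adjusted p = 0.0262), both with adjusted p = 0.185 with an estimated correlation. The median of T cell receptor signalling was 0.11, and its call was lost without CD73 KO replicate 1 (adjusted p = 0.0857, median 0.06) and without WT replicate 3 (adjusted p = 0.203, median 0.07).

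Biosynthetic and metabolic lists lay on the lower side. Nucleotide synthesis fell, with 27 of 28 members lower and a median of -0.20 (adjusted p = 2.40e-09, and adjusted p = 0.185 with an estimated correlation). Gart, Cad, Mthfd1, Ctps and Aprt passed when adjusted over the list alone, with log2 fold changes from -0.41 to -0.35. Over the list alone 12 passed without CD73 KO replicate 3 and 0 without any one of the other 5 libraries, and 0 with library size alone, without robust estimation, with the replicate block, after thinning or with the hypoxia covariate. Oxidative phosphorylation fell with 33 of 34 lower (adjusted p = 2.97e-07, and adjusted p = 0.380 with an estimated correlation), and cholesterol synthesis with 21 of 23 lower (adjusted p = 0.000670, and adjusted p = 0.420 with an estimated correlation). Heat shock genes fell with 17 of 19 lower (adjusted p = 1.68e-05), the unfolded protein response with 20 of 25 lower (adjusted p = 0.000657) and fatty acid metabolism with 21 of 22 lower (adjusted p = 0.00126), each with adjusted p = 0.185 with an estimated correlation. Without CD73 KO replicate 2 the unfolded protein response was not called (adjusted p = 0.0594), its median going from -0.15 to -0.07; it was -0.28 without CD73 KO replicate 1 and -0.08 without CD73 KO replicate 3. The median of cholesterol synthesis, -0.15, was -0.09 and -0.24 without CD73 KO replicates 1 and 2, and that of fatty acid metabolism, -0.11, was -0.18 without CD73 KO replicate 2. Cytotoxic granule genes fell with 15 of 23 lower and a median of -0.15 (adjusted p = 0.0264, and adjusted p = 0.498 with an estimated correlation). Without the library labelled WT replicate 2 the median of that list was 0.02 (adjusted p = 0.349), and its call was also lost without CD73 KO replicate 1 (adjusted p = 0.0784) and CD73 KO replicate 2 (adjusted p = 0.0878).

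The remaining 11 lists did not pass the preset test. They were adenosine handling (adjusted p = 0.419), inhibitory receptors (0.430), exhaustion transcription factors (0.419), cytokines (0.493), chemokine receptors (0.573), costimulation (0.658), glycolysis (0.105), hypoxia (0.809), cell division (0.493), apoptosis and p53 targets (0.183) and ribosomal proteins (0.0839). In the apoptosis and p53 list, Ccng1, Zmat3, Phlda3 and Cdkn1a were lower and Bmf and Trp53inp1 higher when adjusted over the list alone. Lta was lower among cytokines by the same count. The 6 calls of the apoptosis and p53 list went to 0 without CD73 KO replicate 2, 1 without WT replicate 2, 4 without WT replicate 3, where the list itself passed (adjusted p = 0.0202), and 1 after thinning. The count of cytokines went from 1 to 0 without WT replicate 1 or 2 or after thinning, 2 without CD73 KO replicate 2 and 3 without WT replicate 3. Other lists passed the preset test when a library was left out. With an estimated correlation, 0 of 24 lists, apoptosis and p53 targets included, passed without any one library (lowest adjusted p = 0.166). With the hypoxia covariate 0 passed either (lowest adjusted p = 0.0995). Even the interferon list, with all 35 members higher, had an unadjusted p of 0.0327 by camera with an estimated correlation and all 6 libraries. So few libraries leave that test little power, and 0 of 24 does not show that no list changed. By the preset test, glycolysis, with a median of -0.09, fell without CD73 KO replicate 2 (adjusted p = 0.000370, median -0.20), WT replicate 1 (adjusted p = 0.000306, median -0.21) or WT replicate 2 (adjusted p = 0.00529, median -0.14) and with the hypoxia covariate (adjusted p = 0.0124), while its median was 0.10 without WT replicate 3. Hypoxia rose without WT replicate 3 (adjusted p = 0.00115), its median going from 0.02 to 0.29. The hypoxia median was -0.17, -0.12 and -0.06 without CD73 KO replicate 2, WT replicate 1 and WT replicate 2. It was 0.06 and 0.13 without CD73 KO replicates 1 and 3, and the list passed in none of these fits. Ribosomal proteins rose without CD73 KO replicate 2 (adjusted p = 7.45e-05) or WT replicate 3 (adjusted p = 0.00225), their median going from 0.08 to 0.15 and 0.14, and cell division fell without WT replicate 3 (adjusted p = 0.0379, median -0.09 against -0.05).

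**Figure D3:**
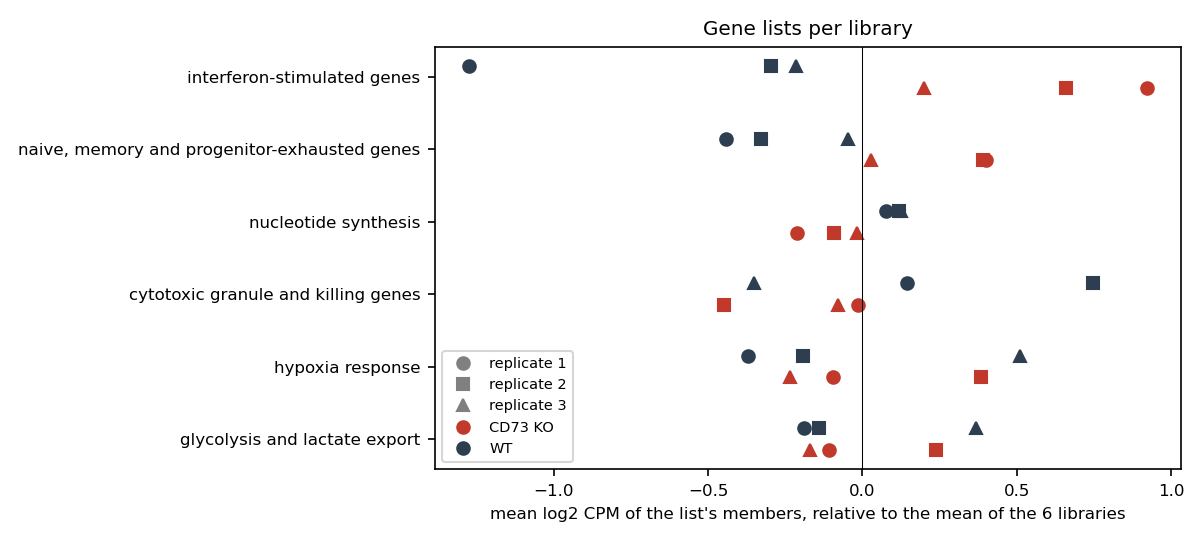
Mean log2 CPM of the members of 6 gene lists in each library, relative to the mean of the 6 libraries. Interferon-stimulated genes lie above 0 in all CD73 KO libraries (0.20 to 0.92) and below 0 in all WT libraries (-1.27 to -0.22), while the hypoxia list is highest in CD73 KO replicate 2 (0.38) and WT replicate 3 (0.51).

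Some markers of other cell types were absent and others were not. Lyz2, Csf1r, C1qa, Spi1, Ms4a1 and Siglech had 0 counts in all 6 libraries, which allows up to 0.155 to 0.433 CPM. Other listed markers were detected in every library. Counts were 4905 to 14845 for Ighm (B cell list) and 431 to 1689 for Ctss (myeloid list). They were 2618 to 8887 for Klrd1 (NK cell list) and 320 to 1943 for Pecam1 (stromal list). The B cell list rose with 5 of 5 tested members higher (adjusted p = 0.0101, and adjusted p = 0.148 with an estimated correlation), Ighd (0.80 ± 0.16) leading. The B cell list also passed fry's test of change in either direction (adjusted p = 0.02525), but not its directional test (adjusted p = 0.0661). The gamma-delta T cell list fell with 4 of 5 lower (adjusted p = 0.0431, and adjusted p = 0.296 with an estimated correlation), Tcrg-C4 (-2.08 ± 0.46) leading. NK cell (adjusted p = 0.442) and CD4 T cell (adjusted p = 0.160) lists did not pass. Myeloid, dendritic, red cell and stromal lists had 2, 3, 2 and 2 tested members and were not tested.

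The libraries also differed in ways that genotype did not follow. The first principal component (33.9% of the variance) placed WT replicates 1 and 2 at -24.9 and -26.8 and WT replicate 3 at 8.71, beside the CD73 KO libraries at 8.14 to 24.7. CD73 KO replicate 2 correlated more closely with WT replicate 3 (Pearson r of log2 CPM across genes 0.986) than with CD73 KO replicate 3 (0.985).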

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

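The number of changed genes depended on the tool and the filter. Without a filter 298 genes were called (223 higher, 75 lower, 120 at least 2-fold), 273 of them among the 12242 genes of the filtered fit; the prior degrees of freedom went from 6.68 to infinite, which removes gene-specific spread. DESeq2 called 99 (79 higher, 20 lower, 48 at least 2-fold), 12 of the 92 added genes being interferon-stimulated; the cause was not tested. With the hypoxia list mean as covariate, chosen after seeing the data, 15 were called (13 higher, 13 at least 2-fold) and Tigit turned to 0.0092; the cause was not tested. The other settings called 5 to 7 genes. With the replicate number as a block 3 genes were higher instead of 5. Same-numbered libraries had correlations of 0.15, -0.17 and 0.01 in their deviations, and differently numbered ones ranged from -0.32 to 0.36. These values do not tell whether the numbers pair samples. Leaving out each replicate gave 4 to 8 changed genes (3 to 6 higher, 1 to 2 lower, 4 to 8 at least 2-fold), with 4 without CD73 KO replicate 2 or WT replicate 2; fewer samples were tested. Nt5e then had log2 fold changes from -2.14 to -1.06 and 11 to 16 lists passed. Calls of Mns1, Gm11868, Gm13456 and Gm5869 held in all 17 alternatives. The list calls went from 13 to 0 with an estimated correlation and to 0 with directional fry; correlation among members is not the whole cause, since the cAMP list lost its call at an estimated correlation of -0.0105, under the preset 0.01. With an estimated correlation 0 lists passed without any one library or with the covariate either, tests also added later. So few libraries leave these tests little power. The odds ratio near Nt5e was 151 within 5 Mb and 45.2 within 20 Mb, and within 10 Mb, in fits added after seeing the data, it was 5.23 without a filter (9 of 133 genes), 6.86 with DESeq2 (4 of 133), 34.6 with library size alone, no robust estimation, the edgeR 4 fit or limma-voom, 43.25 with the replicate block, 27.7 after thinning, 27.0 with the covariate and 0 to 57.5 over the leave-outs; within 5 and 10 Mb the called genes went from 2 to 0 without CD73 KO replicate 2 or 3 or WT replicate 1 or 2. Log2 fold changes crossed 0 when replicates were left out for Pdcd1 (-0.51 to 0.18), Ctla4 (-0.23 to 0.24), Tigit (-0.12 to 0.079) and Mki67 (-0.047 to 0.21), none past the threshold. In data simulated at these library sizes with 3 libraries per group, 25.4% of genes changed 1.5-fold were recovered, and 8.22% of edgeR calls and 14.3% of DESeq2 calls were false. Genes were simulated independently there, so the rates in the real libraries may differ.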

Other observations

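Some genes varied among the libraries without following genotype. Eomes, a transcription factor of effector and memory CD8 T cells, had 283, 21 and 70 counts in the CD73 KO libraries and 387, 324 and 18 in the WT libraries. Fcer1g, a signalling adaptor of Fc receptors, had 32, 9 and 24 against 86, 72 and 6. Hypoxia genes and glycolysis genes were high in other libraries, with list means of 0.38 and 0.24 in CD73 KO replicate 2 and 0.51 and 0.37 in WT replicate 3. These genes were chosen after their values were seen.

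The tests of retrocopies, of markers of other cells, of the label of WT replicate 2 and of the share near Nt5e under settings other than the window were chosen only after those results were seen. Of the 7 changed genes, 2 lie within 10 Mb of Nt5e, Mns1 lies 15.9 Mb from it, and 4 are retrocopies of genes within 10 Mb. Over 17 alternatives the 2, Cyb5r4 and Bckdhb, had log2 fold changes of -1.12 to -0.91 and of 1.21 to 1.51. Their groups do not overlap, so leaving out a library could hardly reverse these directions. The odds ratio of 70.1 for changed genes within 10 Mb is consistent with sequence flanking the knockout allele that differs from WT, as a donor strain would leave, but it rests on Cyb5r4 and Bckdhb, and no gene there was called by edgeR without CD73 KO replicate 2 or 3 or WT replicate 1 or 2 (odds ratio 0), the odds ratio was 5.23 without a filter on low counts and 6.86 with DESeq2, and 11 to 19 genes there had an unadjusted p under 0.05 over the 6 leave-outs. Over 753 tested retrocopies, 4 of 9 with a parent within 10 Mb changed and 0 of 744 with a parent elsewhere (Fisher's exact p = 9.48e-09), but this test was built once the 4 were seen to copy Cyb5r4 and Eef1a1, 3 of them share the parent Eef1a1, at 9.84 Mb, and so it leaves open whether reads of variant parent transcripts were counted at the copies. Loss of CD73 acting on these genes stays open, because genotype and flanking sequence go together here. Of the 10 splits of the 6 libraries, 2 called at least 7 genes, and 2 at least 7 changed 2-fold; grouping CD73 KO replicate 1 with WT replicates 1 and 2 called 19 genes, 14 of them 2-fold, which points to a structure of the libraries other than genotype, and 10 splits are too few for a share under 0.05.

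Interferon-stimulated genes were higher in all CD73 KO libraries. The median stayed at 0.93 with all libraries thinned to one total. Thinning removes reads at random and keeps each gene's expected share, so the median could hardly have fallen. It therefore cannot show whether a difference that goes with depth plays a part. A single library does not account for the higher level, since the lowest median was 0.69, without WT replicate 1. Whether RNA from B, myeloid or dendritic cells plays a part is not settled. In each CD73 KO library 5 of their markers were at 0 CPM, but these were picked with counts known. They show only that those 5 transcripts were not detected. Some other members of these lists were higher in CD73 KO, Ighd by 0.80 ± 0.16 and Ctss by 0.61 ± 0.14. The B cell list rose by camera (5 of 5 higher, adjusted p = 0.0101, and adjusted p = 0.148 with an estimated correlation). The B cell list also passed fry's test of change in either direction (adjusted p = 0.02525). The genotype split gave 13 changed lists and the highest other split 12, with 1 of 10 splits as large, too few for a share under 0.05; the interferon median was at most 0.84 in the others. A difference of cultures in interferon exposure and an effect of genotype remain open and were not tested, and Cgas, a DNA sensor 9.88 Mb from Nt5e, had a log2 fold change of 0.51 ± 0.20 that did not pass (adjusted p = 0.482).

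The library labelled WT replicate 2 had Nt5e at the CD73 KO level. A mislabelled CD73 KO library is argued against by the 4 genes called from the other 5 libraries, Gm13456, Gm11868, Gm5869 and Mns1, since it lay nearer the WT mean at 4 of 4. Gm11868 had 6 counts there, against 203 to 416 in the CD73 KO libraries. A biological range of Nt5e among WT cultures was not tested.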
